A study of Mus musculus with 16 samples.

How the data were processed

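Cells of the left ventricle of male mice of a transverse aortic constriction (TAC) model, in which a narrowed aorta raises the pressure load on the heart, were profiled one by one with polyadenylated RNA sequencing. The labels give 16 mice at 5 disease stages named in weeks, with 2 mice at 0w, 2 at 2w, 7 at 5w, 3 at 8w and 2 at 11w. The labels do not say whether the mice at 0w had surgery, so 0w is used here only as the first stage. Per the labels' protocols, tissue slices were digested either with protease XXIV and collagenase II to enrich myocytes or with a papain enzyme to enrich other cells, and cDNA was made with SMARTScribe reagents and WaferGen oligos before Nextera XT library preparation. This choice can affect the shares of cardiomyocytes and of the other cell types, and its effect was not tested here.

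The deposited table holds counts of unique molecular identifiers (UMIs) per gene and cell, whole numbers that were not normalized, for 36950 genes and 11492 cells. Per the submitters' processing notes, STAR 2.5.2b, featureCounts and Subread 1.4.6-p1 were used and the builds mm10 and GRCh37 were named. Their roles and order, the gene annotation, the use of strand and the way UMIs were collapsed are not given in the sources used here. Gene symbols are those of the table, and genes that overlap, or share reads with pseudogenes or close paralogs, were not separated further. The authors' cell annotation gave each cell's mouse, type and subcluster, and it was used as deposited, with no clustering of its own here. Its types are CM (cardiomyocytes), FB (fibroblasts), EC (endothelial cells), MP (macrophages), T (T cells) and GN, an abbreviation that the labels do not explain. A type was missing for 3 cells, which entered no comparison, and 0 columns lacked a mouse.

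Totals of the matrix without the 34 mitochondrially encoded genes equalled the authors' UMI number for 73.9% of cells, that is for every cell of 9 of the 12 plates that the cell names give. These plates are lettered A to L here, in order of stage. Every cell had at least 501 annotated genes. No further filter on cells was applied, and doublets were not called, so cells of very high UMI number or of mixed types remained in the sums. Mitochondrially encoded genes took 56.0% of all UMIs, and the ribosomal RNA genes among them took 30.6% of all UMIs.

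Cells are not replicates, so counts were summed per mouse and cell type, and the mouse was the replicate. Mice with at least 10 cells of a type entered the fit of that type, 14 for CM, 12 for FB, 13 for EC, 16 for MP and 11 for T. GN cells entered only the comparison of shares. Sums were fitted with edgeR 4.0.16 (filterByExpr, TMM factors, glmQLFit with robust dispersion, two-sided glmQLFTest) in R 4.3.3, 1 fit per type over all stages with no covariate. The 5 contrasts per type were 2w, 5w, 8w and 11w against 0w, and the mean of 8w and 11w against 5w. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are log2 with their standard error, and CPM are the values of edgeR's cpm function on TMM-scaled library sizes, except for sums of markers, cell cycle genes or thymocyte genes, which are scaled to the total of non-mitochondrial UMIs without TMM factors. Intervals, where given, are 95% exact binomial or Poisson intervals and cover counting error only.

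Gene lists were tested with limma 3.58.1 camera on the same sums, with a preset inter-gene correlation of 0.01 and, beside it, with an estimated correlation, adjusted over the 39 lists within a type and contrast. These lists cover pathways of heart failure, states of the non-cardiomyocyte types and markers of other cell types. Of 975 tests, 295 passed with the preset correlation and 3 with an estimated one. Shares of cell types among the annotated cells of a mouse were compared across stages by a permutation test of 100000 permutations of the stage labels over mice with at least 20 cells in the denominator, using Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

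The genes named in the text followed a rule. Per type and contrast these were, of the genes past the threshold with an average log2 CPM of at least 5 and excluding predicted, mitochondrial and ribosomal protein genes, the 5 with the highest and the 5 with the lowest fold change. Up to 4 members of each gene list with the smallest p were added, and a fixed set of genes, such as Nppa in CM, Postn in FB, Vwf in EC and Spp1 in MP, was to be named whatever the result. The text departs from this rule in 3 ways. Genes of that last kind are given as a range outside the contrasts of 11w against 0w and, in CM, of 8w and 11w against 5w; a fold change is left out where a group held 3 or fewer UMIs; and called genes outside the rule, named because few genes passed, are said to be so. The groups, tests, lists, naming rule and a first set of alternatives were fixed before the data were examined. That set holds other scaling factors (RLE), no low-count filter, no mitochondrial genes, at least 20 cells per mouse, the replicate number as a block, DESeq2 1.42.0 and each mouse left out in turn.

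After the tests called almost no gene, 10 further settings per count were tried, all chosen after seeing the data: means of log values over cells, logs of mean values with 0.1 added, shares of cells with a UMI, each cell thinned at random to 1000, 2000 or 4000 non-mitochondrial UMIs, a second draw at 2000, and either 1 or 3 plates left out or only plates with mostly non-cardiomyocytes kept. The results below rest on the tests fixed beforehand, and values of the later settings are named as such. Thinning to 2000 UMIs left out 361 cells, 9 of 0w, 94 of 2w, 109 of 5w, 5 of 8w and 144 of 11w.

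The fit was tested on simulated counts with 200 changed genes, drawn from the means, library sizes and dispersions of the real sums. For 11w against 0w, the test recovered 3.0% of genes changed 8-fold in CM, 1.5% in FB, 0 in EC, 0 in MP and 1.5% in T, and 0 of those changed 2-fold in CM. For 8w and 11w against 5w it recovered 39.4%, 25.8%, 18.2%, 18.2% and 3.0% of the 8-fold changes in CM, FB, EC, MP and T. A count near 0 in these contrasts therefore does not show that genes stayed at the same level. The spread between mice was wide, with a common dispersion of 0.548 in CM, 0.781 in FB, 0.985 in EC, 1.03 in MP and 1.16 in T, and the deepest 5% of cells held a median of 17.2% (CM) to 22.6% (EC) of a mouse's UMIs.

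Plate was nested in stage. Plates A and B held 0w, C and D 2w, F, G and H 5w, I and J 8w, and K and L 11w. Only E held 2 stages (replicate 1 of 5w and 8w). No contrast against 0w can tell stage from plate. P-values measure spread between mice, labeled as individuals. At 0w, 2w and 11w both mice shared plates, so p-values leave out spread between plates and may be too small. Not every list that passed was written out.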

Results

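The series holds 11492 cells from the left ventricles of 16 male TAC mice, of which 5656 were annotated as cardiomyocytes (CM), 1858 as endothelial cells (EC), 1775 as fibroblasts (FB), 1413 as macrophages (MP), 606 as T cells (T) and 181 as GN. The mice gave between 113 cells (5w replicate 2) and 1269 cells (0w replicate 1), and between 3441317 and 121599183 UMIs, with a median of 41573.5 UMIs per cell. Mitochondrially encoded genes took from 17.3% (5w replicate 2) to 84.9% (5w replicate 7) of a mouse's UMIs. At 5w, replicates 2 and 3, on plate F, had 0 annotated cardiomyocytes, while cardiomyocytes made up 93.6% and 93.8% of the cells of plates G and H, which held replicates 4 to 7. The CM of 0w were mostly on plate A (912, and 22 on plate B), those of 5w on plates G and H (1163 and 799, and 54 in 5w replicate 1) and those of 11w on plate K (391, and 7 on plate L). Per cell, the non-mitochondrial UMIs of the matrix came to a median of 0.545, 0.805 and 0.481 of the authors' UMI number on plates G, H and K. On plates A, B and L they equalled it. Every CM comparison with 5w or 11w therefore rests mainly on plates whose non-mitochondrial totals differ from the authors' numbers, and none was run without them. The comparisons by stage ask how each cell type of the pressure-loaded ventricle differed from its state at 0w, and how the late stages (8w and 11w) differed from 5w.

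Fibroblasts, the matrix-producing cells of the heart, made up 16.7% ± 0.0899 (SD, n = 2) of annotated non-cardiomyocytes at 0w, 22.9% ± 7.46 (n = 2) at 2w, 22.4% ± 10.1 (n = 7) at 5w, 38.5% ± 9.31 (n = 3) at 8w and 48.7% ± 1.31 (n = 2) at 11w. Endothelial cells made up 47.2% ± 12 at 0w and 25.5% ± 0.290 at 11w. Macrophages made up 19.5% ± 3.38 at 0w, 40.5% ± 15.2 at 5w and 16.8% ± 6.07 at 11w, and T cells made up 15.7% ± 8.61 at 0w and 5.38% ± 1.94 at 11w. None of these shares passed the test across stages. Over the 6 shares tested, the permutation test gave p = 0.0114 for FB (adjusted p = 0.0685). The adjusted p was 0.163 for EC, 0.163 for MP, 0.532 for T, 0.677 for GN and 0.831 for CM among all cells. Leaving out 5w replicate 1, 5w replicate 3 or 8w replicate 1 brought 1 share past the threshold and leaving out 5w replicate 7 brought 2. The FB share of single mice at 5w ran from 11.6% (exact 95% interval 3.89 to 25.1, 5 of 43 cells) to 35.2% (26.8 to 44.4, 43 of 122 cells).

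Within the cell types, the shares of 2 of the 44 subclusters tested differed across stages, both of cardiomyocytes. Subcluster CM1 held 65.1% ± 11.0 (SD, n = 2) of CM at 0w and between 0.268% and 1.75% on average at the later stages. CM11 held 70.8% ± 17.8 (n = 2) of CM at 11w and 0.443% at 0w (permutation test, adjusted p = 0.0486 for each). Both followed plates as well as stages: 92.8% of CM1 cells were on plate A and 64.2% of CM11 cells on plate K. The number of subclusters past the threshold was 0 without any one of the mice except 5w replicate 2, 5w replicate 3 and 8w replicate 1 (2 each) and 8w replicates 2 and 3 (4 each).

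In cardiomyocytes at 2w, levels of stress genes lay above those of 0w in both mice, but no gene passed the test. Ankrd1, a cardiac stress gene of the sarcomere and nucleus, stood at 1510 and 1312 CPM at 2w against 410 and 434 CPM at 0w (log2 fold change 1.74 ± 0.96 SE). Nppa, which encodes atrial natriuretic peptide, had a log2 fold change of 2.65 ± 1.66, and Acta1, the skeletal muscle actin of the fetal heart, one of 1.86 ± 1.25. As groups, CM genes of the extracellular matrix rose at 2w (median log2 fold change 1.06, 36 of 43 members positive, camera adjusted p = 3.2e-09, adjusted p = 0.179 with an estimated correlation, 1 member past the threshold adjusted over the list alone). So did the fetal and hypertrophy genes (median 1.12, 17 of 18 positive, adjusted p = 0.000873, adjusted p = 0.72 with an estimated correlation, 0 adjusted over the list alone). MHC class II genes, which present antigen, rose too (median 2.59, 7 of 7 positive, adjusted p = 9.59e-05, adjusted p = 0.456 with an estimated correlation). Markers of fibroblasts (median 0.79, adjusted p = 0.0083) and macrophages (median 1.61, adjusted p = 0.0326) rose in the same CM sums. These had adjusted p = 0.681 and adjusted p = 0.72 with an estimated correlation. The fibroblast marker call was lost without 2w replicate 1 (adjusted p = 0.119) and the macrophage marker call without 0w replicate 1 or 2w replicate 1 (adjusted p = 0.11 and 0.0904). Atrial markers (median 3.81, 5 of 5 positive, adjusted p = 0.00681) and genes of resting fibroblasts (median 0.51, 17 of 20 positive, adjusted p = 0.0379) rose in them too, and immediate early genes, which respond to cell dissociation, fell (median -0.60, 3 of 25 positive, adjusted p = 9.59e-05). These had adjusted p = 0.681, 0.72 and 0.72 with an estimated correlation. The atrial call was lost without 2w replicate 1 (adjusted p = 0.273), and that of resting fibroblasts without 2w replicate 1 or 0w replicate 2 (0.256 and 0.0911) and with RLE factors (0.0562). The 7 genes named beforehand in CM ran from 0.10 (Atp2a2) to 2.65 (Nppa) at 2w. edgeR called 0 of 15893 genes, with 479 at an unadjusted p under 0.05 and 12 by DESeq2.

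As lists, CM genes of energy metabolism lay lower than at 0w at 5w and, for fatty acid oxidation, at 8w. Genes of fatty acid oxidation, the main fuel pathway of the heart, fell at 5w (median -0.78, 4 of 28 positive, camera adjusted p = 2.61e-05, adjusted p = 0.853 with an estimated correlation). At 8w they fell as well (median -0.73, 2 of 28 positive, adjusted p = 2.91e-08, adjusted p = 0.505 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell at 5w (median -0.56, 6 of 52 positive, adjusted p = 4.77e-07, adjusted p = 0.853 with an estimated correlation). They also passed as lower at 8w (median -0.36, 12 of 52 positive, adjusted p = 0.00122, adjusted p = 0.836 with an estimated correlation). This call was lost without 8w replicate 1 (adjusted p = 0.992) or 0w replicate 2 (adjusted p = 0.0596), and without both mice of plate E (5w replicate 1 and 8w replicate 1), a setting chosen after seeing the data (median -0.08, 23 of 52 positive, adjusted p = 0.901). In that setting the 5w call of fatty acid oxidation held with a median of -0.49 (adjusted p = 0.000159, adjusted p = 0.507 with an estimated correlation). Ech1, of fatty acid oxidation, stood at 34.3 CPM in 5w replicate 1 and at 241 to 439 CPM in the other 4 mice at 5w, against 226 and 221 CPM at 0w. It was picked here after its values were seen. Adjusted over the list alone, 1 gene of oxidative phosphorylation at 5w and 1 of fatty acid oxidation at 8w passed. Matrix genes (median 1.17, 37 of 43 positive, adjusted p = 1.84e-08) and myofibroblast genes (median 1.97, 14 of 17 positive, adjusted p = 2.15e-06) rose at 8w. Each had adjusted p = 0.0702 with an estimated correlation, with 1 and 7 adjusted over the list alone. Markers of mural cells, which wrap vessels, rose in CM at 5w (median 1.90, 8 of 8 positive, adjusted p = 2.47e-05, adjusted p = 0.78 with an estimated correlation).

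In the same CM sums at 5w, endothelial markers (median 0.86, 7 of 7 positive, adjusted p = 0.0025) and genes of resting fibroblasts (median 0.82, 19 of 20 positive, adjusted p = 0.00166) rose, each with adjusted p = 0.853 with an estimated correlation. The second call was lost without 5w replicate 1 (adjusted p = 0.235) and without plate E (adjusted p = 0.217). At 8w, markers of fibroblasts (median 0.97, 7 of 7 positive, adjusted p = 0.00893), mural cells (median 1.20, 8 of 8 positive, adjusted p = 0.00324) and endothelial cells (median 0.77, 7 of 7 positive, adjusted p = 0.0112) rose in CM, and those of cardiomyocytes fell (median -0.84, 0 of 7 positive, adjusted p = 0.00893). With an estimated correlation they had adjusted p = 0.505, 0.505, 0.636 and 0.68. These 4 calls were lost without 8w replicate 1 (adjusted p = 0.138, 0.138, 0.713 and 0.459), without 0w replicate 2 (0.0596, 0.0672, 0.116 and 0.0596) and without plate E (0.118, 0.118, 0.673 and 0.157). Genes of resting fibroblasts also rose at 8w (median 1.02, 19 of 20 positive, adjusted p = 8.95e-06, adjusted p = 0.505 with an estimated correlation). Without plate E they had a median of 0.35 (adjusted p = 0.00543, adjusted p = 0.337 with an estimated correlation), matrix genes one of 0.70 (adjusted p = 4.77e-09, adjusted p = 0.09 with an estimated correlation) and myofibroblast genes one of 1.73 (adjusted p = 1.11e-09, adjusted p = 0.0591 with an estimated correlation).

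Of the 7 genes named beforehand in CM, log2 fold changes ran from -0.68 (Myh6) to 2.24 (Nppa) at 5w and from -1.22 (Atp2a2) to 3.41 (Nppa) at 8w, and none passed. Nppb, which encodes brain natriuretic peptide, was at 1.15 ± 1.37 at 5w. edgeR called 0 genes in either contrast, with 1052 and 735 at an unadjusted p under 0.05 and 91 and 4 by DESeq2. Without 5w replicate 1 it called 13 at 5w. The cardiomyocyte sums of plate E (5w replicate 1, 54 cells, and 8w replicate 1, 123 cells) stood apart. Myh6, the main myosin of the adult ventricle, was at 253 and 306 CPM against 959 to 4906 CPM in the other 12 mice. Markers of fibroblasts, endothelial cells and macrophages together were at 9640 and 7890 CPM against 1600 to 3450 CPM. Without these 2 mice, 84 genes passed at 5w and 3 at 8w. Among them was the metallothionein Mt1, which binds zinc and copper, at -1.93 ± 0.20 (adjusted p = 0.00254) and -2.12 ± 0.25 (adjusted p = 0.0115). The 5w count was then 10 and 0 without 0w replicates 1 and 2, and 22, 24 and 39 without 5w replicates 5, 6 and 7. The 8w count was 0 without 0w replicate 1, 0w replicate 2 or 8w replicate 3 and 8 without 8w replicate 2.

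At 11w, TMM-scaled levels of stress and fetal genes lay above those of 0w in the CM sums, mostly of plate K, and levels of energy metabolism below, with no single gene past the test. TMM factors were 1.37 and 1.379 at 0w and 0.2595 and 0.3574 at 11w. In CPM pooled over mice without these factors, mitochondrial genes included, Ankrd1 went from 575 at 0w to 1060 at 11w, Acta1 from 241 to 113 and Acaa2 from 200 to 14.4. In cells thinned to 2000 non-mitochondrial UMIs they went from 1510 to 6290, from 605 to 665 and from 490 to 91.5. With TMM factors, Ankrd1 stood at 2914 and 3671 CPM against 410 and 434 CPM at 0w (log2 fold change 2.96 ± 1.01, adjusted p = 0.547). Log2 fold changes were 4.58 ± 1.81 for Nppa, 2.79 ± 1.64 for Nppb, 2.81 ± 1.22 for Myh7, the slow myosin of the fetal ventricle, and 1.21 ± 1.23 for Acta1. Myh6 stood at -0.66 ± 0.79 and Atp2a2, the calcium pump of the sarcoplasmic reticulum, at -1.47 ± 0.79. Fetal and hypertrophy genes rose as a group in CM (median 1.37, 15 of 18 positive, camera adjusted p = 2.73e-05, adjusted p = 0.532 with an estimated correlation, 0 adjusted over the list alone). Matrix genes rose as well (median 1.32, 38 of 43 positive, adjusted p = 1.06e-10, adjusted p = 0.132 with an estimated correlation, 2 adjusted over the list alone). Among them were Postn, a matrix protein of remodelling tissue, at 3.72 ± 0.65, Col8a1 at 3.09 ± 0.78, Mfap4 at 3.50 ± 1.07 and Cilp at 4.29 ± 1.32. Fibroblast markers (median 0.68, 7 of 7 positive, adjusted p = 0.0134) and genes of resting fibroblasts (median 0.60, 13 of 20 positive, adjusted p = 0.0306) rose in the same CM sums, with adjusted p = 0.532 and 0.608 with an estimated correlation. The first call was lost without 11w replicate 1 or 2 and the second without 0w replicate 2 or 11w replicate 1 or 2. Genes of fatty acid oxidation fell (median -0.86, 2 of 28 positive, adjusted p = 8.94e-05, adjusted p = 0.608 with an estimated correlation, 2 adjusted over the list alone). Acaa2, a thiolase of that pathway, was at -1.58 ± 0.42. Nuclear genes of oxidative phosphorylation (median -0.74, 0 of 52 positive, adjusted p = 7.04e-06) and of the tricarboxylic acid cycle (median -0.93, 0 of 20 positive, adjusted p = 0.000681) fell too. Each had adjusted p = 0.608 with an estimated correlation and 0 adjusted over the list alone. Their members Uqcrc2 (-1.12 ± 0.45), Ndufs3 (-1.26 ± 0.52), Suclg2 (-2.09 ± 0.70) and Suclg1 (-1.35 ± 0.49) did not pass singly.

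In the same contrast, TMM-scaled mitochondrially encoded genes (median 2.21, 12 of 12 positive, 9 adjusted over the list alone) and erythroid markers, the genes of red blood cells (median 2.99, 6 of 6 positive), rose in CM. They had camera adjusted p = 5.57e-11 and 0.00201, and 0.337 and 0.532 with an estimated correlation. The second call was lost without 11w replicate 2. Unscaled, mitochondrial genes took a median of 64.5% of a cell's UMIs on plate A and 83.0% on plate K. edgeR called 0 of 15893 genes at 11w, with 1393 at an unadjusted p under 0.05 and 144 by DESeq2. Without plate E, which holds no mouse of either stage but adds to the shared estimate of the spread, 135 genes passed, 79 higher and 56 lower. In that fit, chosen after seeing the data, Ankrd1 rose by 2.96 ± 0.32 (adjusted p = 0.00482). Nppa rose there by 4.57 ± 0.81 (adjusted p = 0.0335), Nppb by 2.78 ± 0.39 (adjusted p = 0.0153) and Myh7 by 2.80 ± 0.41 (adjusted p = 0.0159). Acaa2 changed by -1.59 ± 0.32 there (adjusted p = 0.0424). That count went to 0 without 0w replicate 1 or without 0w replicate 2, and to 627 and 983 without 11w replicate 1 and 11w replicate 2.

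Against 5w, 3 CM genes passed at 8w and 11w, all higher. Postn rose by 2.83 ± 0.40 (adjusted p = 0.0206), from 6.76 ± 2.24 CPM (SD, n = 5) at 5w to 41.8 ± 7.52 (n = 3) at 8w and 56.0 ± 26 (n = 2) at 11w. Nmrk2, a nicotinamide riboside kinase of NAD synthesis, rose by 4.33 ± 0.63 (adjusted p = 0.0226), from 0.969 ± 0.746 CPM at 5w to 12.4 ± 6.36 at 8w and 33.9 ± 27.6 at 11w. The predicted gene Gm12155 rose by 3.27 ± 0.45 (adjusted p = 0.0206). Nmrk2 and Gm12155 fall outside the naming rule and were named after their values were seen. Within plate E, the only plate with both stages, 8w replicate 1 and 5w replicate 1 stood at 33.7 against 3.14 CPM for Postn, 5.72 against 0.224 for Nmrk2 and 102 against 50.3 for Gm12155. Both entered this fit, so this is no independent check. Of 345 genes called once these 2 mice were left out and with at least 10 UMIs in them, 42.9% had the same sign between them, against 47.4% of all genes. Ankrd1 (2.55 ± 0.63, adjusted p = 0.197), Nppa (1.76 ± 1.02), Nppb (1.36 ± 0.99), Acta1 (1.01 ± 0.78), Myh7 (0.91 ± 0.73), Myh6 (-0.17 ± 0.50) and Atp2a2 (-1.03 ± 0.50) did not pass.

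Matrix genes rose together in CM from 5w to the late stages (median 0.77, 33 of 43 positive, camera adjusted p = 1.43e-09, adjusted p = 0.238 with an estimated correlation, 10 adjusted over the list alone). Mfap5 was at 2.48 ± 0.46 and Mfap4 at 2.51 ± 0.67. Fetal and hypertrophy genes rose too (median 1.02, 16 of 18 positive, adjusted p = 1.52e-05, adjusted p = 0.597 with an estimated correlation, 3 adjusted over the list alone). Erythroid markers rose (median 2.29, 6 of 6 positive, adjusted p = 0.000105) and mural markers fell (median -1.30, 1 of 8 positive, adjusted p = 6.12e-05). Each had adjusted p = 0.464 with an estimated correlation, with 5 and 3 adjusted over the list alone. Neutrophil markers rose (4 of 5 positive, adjusted p = 0.0144, adjusted p = 0.288 with an estimated correlation), a call lost without 5w replicate 4 (adjusted p = 0.109). edgeR called 3 genes, with 2078 at an unadjusted p under 0.05 and 474 by DESeq2. The count was 70 without 5w replicate 1, 0 without 5w replicate 4, 5 or 6, 8w replicate 2 or 3, or 11w replicate 2, 1 without 5w replicate 7 and 2 without 11w replicate 1. Without plate E, chosen after seeing the data, it was 419. That count was 122, 209, 123 and 179 without 5w replicates 4 to 7. Where Postn lost its call in CM with a mouse left out, its adjusted p lay between 0.0628 and 0.16. That of Nmrk2 lay between 0.0514 and 0.185 and that of Gm12155 between 0.0654 and 0.135.

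**Figure D1:**
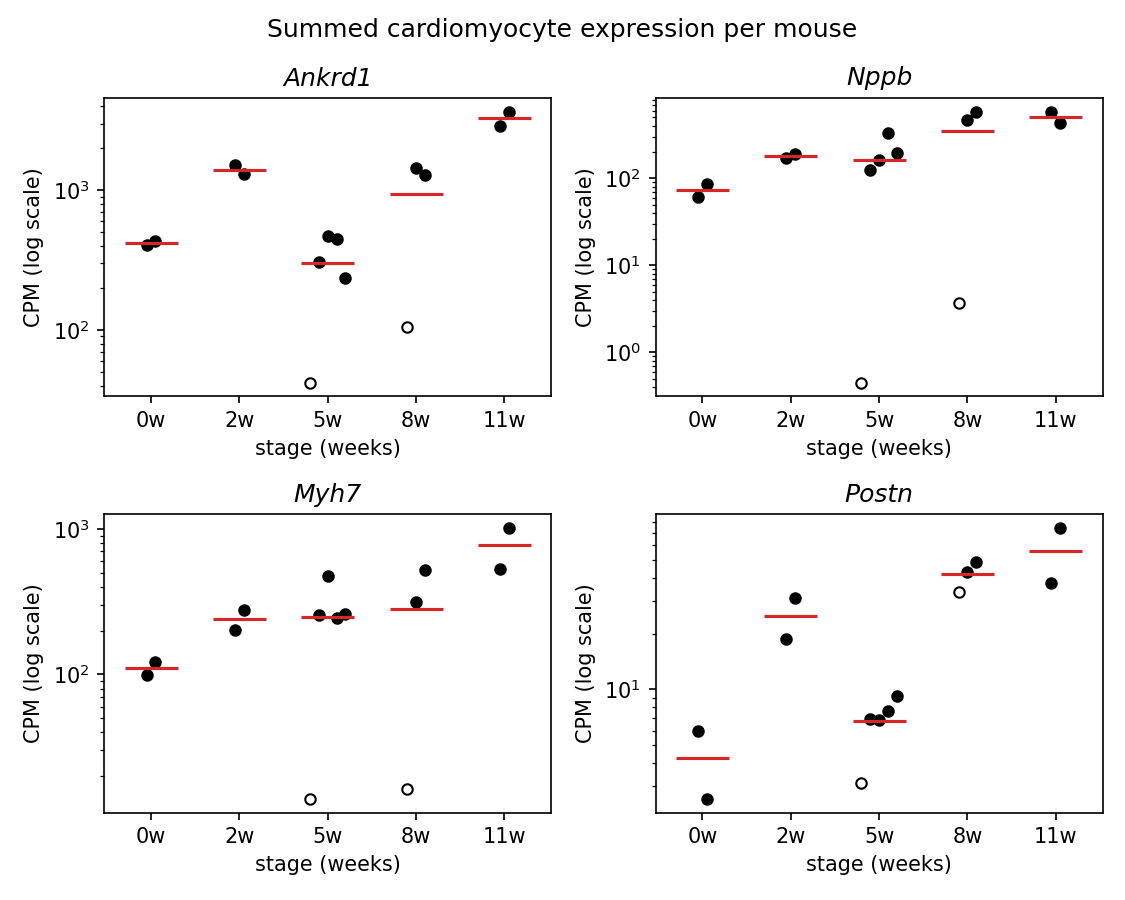
TMM-scaled CPM of Ankrd1, Nppb, Myh7 and Postn in the summed CM of 14 mice, on a log axis, by stage in weeks. Each point is a mouse, open circles are the 2 of plate E and red bars are stage means. The scaled Ankrd1 values at 11w (2914 and 3671 CPM) lie above those of every other stage. Plate E mice lie lowest for Ankrd1, Nppb and Myh7. Pooled without TMM factors, Ankrd1 was at 2700 (2w), 1200 (8w) and 1060 CPM (11w).

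In fibroblasts at 2w and 11w, the lists of matrix and myofibroblast genes stood above their 0w levels, with no single gene past the test. Postn was at 729 and 1024 CPM at 2w and 737 and 1707 CPM at 11w against 69.6 and 125 CPM at 0w (log2 fold changes 3.17 ± 1.04 and 3.65 ± 1.06). Col3a1, a fibrillar collagen, had log2 fold changes of 2.49 ± 0.53 at 2w (adjusted p = 0.402) and 1.42 ± 0.51 at 11w. FB matrix genes rose as a group at 2w (median 1.22, 37 of 44 positive, camera adjusted p = 9.6e-10, adjusted p = 0.36 with an estimated correlation, 8 adjusted over the list alone). They rose at 11w too (median 0.90, 39 of 44 positive, adjusted p = 1.61e-08, adjusted p = 0.327 with an estimated correlation, 4 adjusted over the list alone). Members with the smallest p were Fstl1 (1.83 ± 0.43) and Lum (2.10 ± 0.55) at 2w. At 11w they were Comp (8.44 ± 1.73), a cartilage matrix protein, Timp1 (5.08 ± 1.17), an inhibitor of metalloproteinases, and Cilp (4.42 ± 1.20). Myofibroblast genes rose at 2w (median 2.43, adjusted p = 0.000265, adjusted p = 0.36 with an estimated correlation, 3 adjusted over the list alone). They rose again at 8w (median 2.62, adjusted p = 0.00025, adjusted p = 0.892 with an estimated correlation, 3 adjusted over the list alone) and 11w (median 2.89, 16 of 17 positive, adjusted p = 3.29e-09, adjusted p = 0.327 with an estimated correlation, 4 adjusted over the list alone). The 8w call was lost without 0w replicate 1 (adjusted p = 0.08) or 8w replicate 3 (adjusted p = 0.059). Meox1, a transcription factor of activated fibroblasts, was at 3.08 ± 0.99 and 3.07 ± 0.99 at 2w and 11w and Ddah1 at 6.17 ± 1.44 at 11w. In the same FB sums at 2w, atrial (5 of 5 positive, adjusted p = 0.035) and fibroblast markers (5 of 7, adjusted p = 0.0413) and heat shock genes (14 of 15, adjusted p = 0.0498) rose, and mural markers (0 of 8, adjusted p = 0.0227) and capillary genes (3 of 18, adjusted p = 0.00592) fell. With an estimated correlation they had adjusted p = 0.36, 0.36, 0.693, 0.36 and 0.596. These calls were lost without 0w replicate 1 (adjusted p = 0.177, 0.105, 0.105, 0.0898 and 0.0684). All but the mural call were lost without 2w replicate 1 (0.259, 0.181, 0.404 and 0.266) and all but the capillary call with cells thinned to 2000 UMIs (0.056, 0.252, 0.494 and 0.0899). The fibroblast and heat shock calls were lost without 0w replicate 2 (0.118 and 0.0829) and with RLE factors (0.0563 and 0.0609), and the mural call without 2w replicate 2 (0.165). At 11w mitochondrially encoded genes rose (9 of 11, adjusted p = 0.000831) and capillary genes fell (2 of 18, adjusted p = 6.57e-05), with adjusted p = 0.708 and 0.347 with an estimated correlation, the first call lost without 11w replicate 2 (0.102).

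At 11w the other FB genes named beforehand were Col1a1 (0.77 ± 0.56, at 236 and 531.6 CPM against 204.3 and 246.9), Acta2, the smooth muscle actin of myofibroblasts (1.95 ± 1.43), and Pdgfra, a receptor marking fibroblasts (-0.65 ± 0.54), none past the test. The 5 genes ran from -0.57 (Pdgfra) to 3.17 (Postn) at 2w, from -1.05 (Pdgfra) to 0.85 (Col3a1) at 5w and from -0.52 (Pdgfra) to 3.10 (Postn) at 8w. Interferon response genes rose at 2w (median 1.36, 28 of 30 positive, camera adjusted p = 0.00592, adjusted p = 0.778 with an estimated correlation). They also rose at 11w (median 1.65, 26 of 30 positive, adjusted p = 2.31e-06, adjusted p = 0.708 with an estimated correlation), with 0 members adjusted over the list alone at either stage. Without 2w replicate 1 the 2w call was lost and its direction turned (adjusted p = 0.674). At 11w, heat shock genes (15 of 15 positive, adjusted p = 0.0277), and endocardial and lymphatic markers (5 of 5 and 7 of 7 positive, adjusted p = 0.0117 each) rose in the same FB sums, with adjusted p = 0.716, 0.327 and 0.327 with an estimated correlation. The first call was lost without 0w replicate 1, 0w replicate 2 or 11w replicate 2 (adjusted p = 0.111, 0.0513 and 0.947), the second without 0w replicate 2 (0.0513) and the third without 0w replicate 1 (0.0722) and with thinned cells (0.352). edgeR called 0 of 15427 FB genes at 2w, 5w, 8w and 11w, with 1680, 1505, 1433 and 1200 at an unadjusted p under 0.05 and 454, 286, 286 and 223 by DESeq2. Leaving out 5w replicate 1 gave 2 at 5w and leaving out 8w replicate 1 gave 1 at 8w. With cells thinned to 2000 UMIs, a setting chosen after seeing the data, 8 genes passed at 2w and 15 at 11w. Among them was Cst6, a protease inhibitor (4.39 ± 0.92 at 2w, adjusted p = 0.0443, and 5.16 ± 0.92 at 11w, adjusted p = 0.0123). The 2w count then fell to 1 without 0w replicate 1, 2w replicate 1 or 2w replicate 2 and to 3 without 0w replicate 2. The 11w count fell to 2, 3 and 1 without 0w replicate 1, 0w replicate 2 and 11w replicate 2.

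From 5w to the late stages, FB myofibroblast genes rose (median 1.80, 16 of 17 positive, camera adjusted p = 5.62e-08, adjusted p = 0.16 with an estimated correlation, 4 adjusted over the list alone). Postn was at 3.03 ± 0.81 (adjusted p = 0.339), Lox, which cross-links collagen, at 3.73 ± 1.00, Ctgf at 2.15 ± 0.72 and Timp1 at 2.97 ± 0.83. Acta2 was at 2.30 ± 1.13, and the 5 genes named beforehand ran from -0.07 (Col3a1) to 3.03 (Postn). Subclusters were not separated: FB5 held 54.8% ± 46.3 (SD, n = 3) of FB at 5w, 2.33% at 8w and 0.621% at 11w. Genes of resting fibroblasts fell (median -0.67, 6 of 20 positive, adjusted p = 0.0226, adjusted p = 0.441 with an estimated correlation, 3 up and 8 down adjusted over the list alone). That call was lost without 5w replicate 3, 8w replicate 3 or 11w replicate 2. Sarcomere genes, which belong to cardiomyocytes, rose in the same FB sums (median 1.76, 21 of 21 positive, adjusted p = 2.58e-26, adjusted p = 0.16 with an estimated correlation, 18 adjusted over the list alone). They had fallen at 5w against 0w (median -1.58, 0 of 21 positive, adjusted p = 3.29e-15, adjusted p = 0.444 with an estimated correlation, 11 adjusted over the list alone). Mitochondrially encoded genes rose in these FB sums from 5w to the late stages (median 1.79, 10 of 11 positive, adjusted p = 4.46e-16, adjusted p = 0.16 with an estimated correlation) and fell at 5w against 0w (median -1.35, 2 of 11 positive, adjusted p = 1.85e-06, adjusted p = 0.444 with an estimated correlation). In cells thinned to 2000 UMIs, the 7 cardiomyocyte markers summed to 819 to 2510 CPM in the FB of the 6 plates with under 20% cardiomyocytes and to 16300 to 52600 CPM on the 5 plates with over 70%. edgeR called 0 FB genes, with 1582 at an unadjusted p under 0.05 and 227 by DESeq2. The count was 7 without 5w replicate 1 or 8w replicate 1. Thinned to 2000 UMIs, 9 genes passed, among them Ankrd1 (4.02 ± 0.67, adjusted p = 0.0402). That count was 0 without 5w replicate 2, 5w replicate 3 or 8w replicate 3 and 2 without 8w replicate 2. It was 98 and 71 without 5w replicate 1 and 8w replicate 1.

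**Figure D2:**
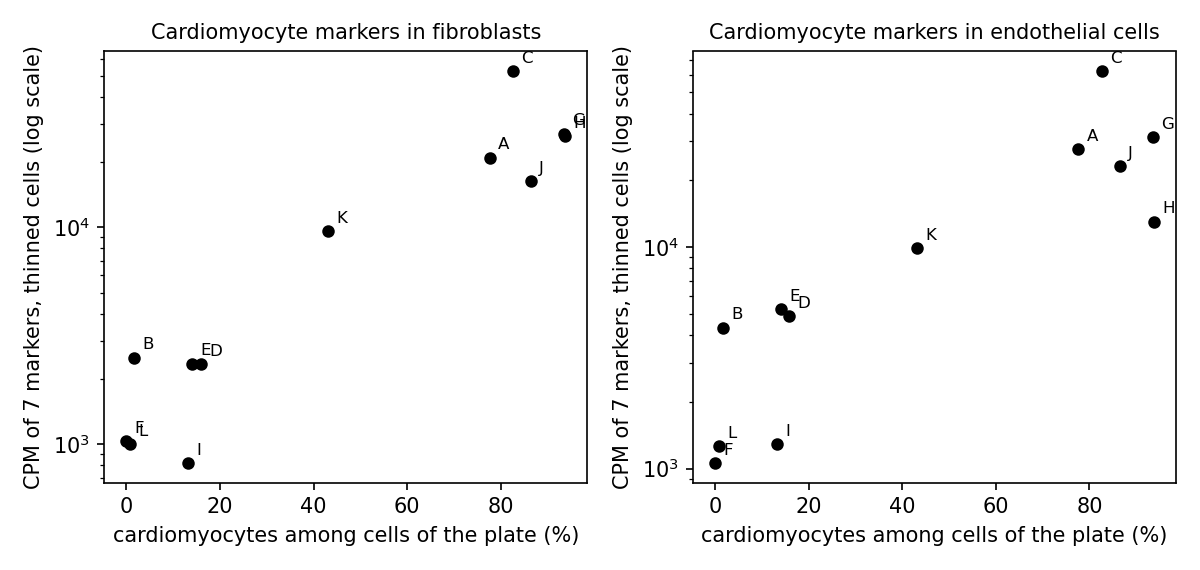
Summed CPM of 7 cardiomyocyte markers in annotated fibroblasts and endothelial cells of each plate, with cells thinned to 2000 UMIs, against the percentage of cardiomyocytes among the plate's cells; each point is a plate, named by its letter, and the CPM axis is on a log scale. Fibroblasts of the 6 plates with under 20% cardiomyocytes lie between 819 and 2510 CPM and those of the 5 plates with over 70% between 16300 and 52600 CPM.

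EC at 11w held more transcript of activation genes and less of capillary genes than at 0w. Subclusters were not separated: EC1 was 51.3% of EC at 0w and 0% at 11w, EC9 2.06% and 47.6%. Vwf, the von Willebrand factor gene of larger vessels, stood at 529 and 562 CPM against 49.7 and 60.4 CPM (log2 fold change 3.31 ± 1.14, adjusted p = 0.424). Plvap, of fenestrated endothelium, stood at 120 and 172 CPM against 2.34 and 2.42 CPM (5.93 ± 1.49), and Vcam1, a leukocyte adhesion molecule, at 3.05 ± 1.08. Fabp4, a fatty acid carrier of capillaries, was at -1.43 ± 0.68 and Pecam1, common to endothelium, at 0.40 ± 0.71. EC activation genes rose (median 1.73, 16 of 22 positive, camera adjusted p = 1.18e-05, adjusted p = 0.163 with an estimated correlation, 4 adjusted over the list alone). Capillary genes fell (median -1.16, 1 of 18 positive, adjusted p = 7.39e-05, adjusted p = 0.449 with an estimated correlation, 1 adjusted over the list alone). Car4 was at -4.41 ± 1.33, Rgcc at -2.05 ± 0.70 and Timp4 at -3.53 ± 1.34. Sele and Selp, the selectins that slow leukocytes, stood at 176 and 312 CPM and at 29.3 and 74.3 CPM at 11w, against 0.895 and 5.99 CPM and 1.32 and 0.263 CPM at 0w. In the same EC sums, immediate early genes (median 0.60, 23 of 25 positive, adjusted p = 0.00166) and heat shock genes (median 0.94, 14 of 15 positive, adjusted p = 0.0026) rose, lists that can respond to tissue handling. So did endocardial markers (4 of 6 positive, adjusted p = 0.00864) and mitochondrially encoded genes (median 1.80, 10 of 11 positive, adjusted p = 1.18e-05), while macrophage markers fell (0 of 6 positive, adjusted p = 0.0285). With an estimated correlation they had adjusted p = 0.521, 0.418, 0.388, 0.388 and 0.498. With cells thinned to 2000 UMIs, a setting chosen after seeing the data, the first 2 calls were lost (adjusted p = 0.134 and 0.139). That of heat shock was also lost without 11w replicate 2 and that of endocardial markers without 0w replicate 1 or 2. That of macrophage markers was lost without any one mouse of 0w or 11w. Lymphatic markers (7 of 7 positive, adjusted p = 0.000459) and sarcomere genes (18 of 21 positive, adjusted p = 0.00276) rose in these EC too, with adjusted p = 0.163 and 0.76 with an estimated correlation, the second lost with thinned cells, where its direction turned (0.972).

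At 2w, interferon response genes rose in EC (median 1.82, 29 of 30 positive, camera adjusted p = 1.85e-06, adjusted p = 0.682 with an estimated correlation, 0 adjusted over the list alone). The chemokine Cxcl9 was at 3.84 ± 1.48 and the guanylate-binding proteins Gbp2 at 3.19 ± 1.26 and Gbp3 at 3.47 ± 1.47. Markers of NK cells (3 of 3 positive, adjusted p = 0.00111) and B cells (4 of 4 positive, adjusted p = 0.0362) and sarcomere genes (20 of 21 positive, adjusted p = 0.0133) rose in the same EC sums, with adjusted p = 0.682, 0.682 and 0.72 with an estimated correlation. The NK call was lost without 2w replicate 2 and the B cell call without 0w replicate 1 or 2 or 2w replicate 2. That of the sarcomere was lost without 0w replicate 1 and with cells thinned to 2000 UMIs (adjusted p = 0.0689). At 11w the interferon genes rose again (median 1.62, 27 of 30 positive, adjusted p = 1.94e-05, adjusted p = 0.584 with an estimated correlation, 0 adjusted over the list alone), a call lost without 11w replicate 2 (adjusted p = 0.252). Vwf was at 1.17 ± 1.05 at 2w, 2.11 ± 1.00 at 5w and 2.14 ± 1.03 at 8w, the highest of the 3 genes named beforehand at each of these stages. The lowest were Pecam1 at 2w (0.56) and Fabp4 at 5w (-1.27 ± 0.56) and 8w (-0.46). Cell cycle genes fell at 5w (median -2.36, 4 of 25 positive, adjusted p = 0.000477, adjusted p = 0.281 with an estimated correlation, 1 adjusted over the list alone). They fell again at 8w and 11w (medians -1.56 and -2.36, adjusted p = 0.000537 and 3.14e-05). With an estimated correlation they had adjusted p = 0.285 and 0.163, with 4 and 0 adjusted over the list alone. Macrophage markers fell in EC at 5w and 8w (0 of 6 positive each, adjusted p = 0.0117 and 0.00938, adjusted p = 0.428 and 0.36 with an estimated correlation), the 5w call being lost without 0w replicate 1 or 5w replicate 7 (0.0689 and 0.0851). Cardiomyocyte markers rose in EC at 5w (median 1.12, 7 of 7 positive, adjusted p = 0.0239, adjusted p = 0.695 with an estimated correlation). At 8w these rose as well (median 1.56, adjusted p = 0.000389, adjusted p = 0.36 with an estimated correlation). The 5w call was lost without 0w replicate 1, 5w replicate 5 or 5w replicate 7 (adjusted p = 0.0923, 0.792 and 0.126) and with cells thinned to 2000 UMIs (adjusted p = 0.215). The 8w call was lost without 8w replicate 2 (adjusted p = 0.073).

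A single EC gene passed against 0w, the predicted gene Gm12666 at 5w (-6.26 ± 1.07, adjusted p = 0.0426), named after its value was seen. It was at 369 and 298 CPM at 0w and 0 to 6.82 CPM in the 4 mice at 5w. Leaving out any one of these 6 mice raised its adjusted p to between 0.113 and 0.608. edgeR called 0, 1, 0 and 0 of 14532 EC genes at 2w, 5w, 8w and 11w, with 1206, 1418, 1330 and 1130 at an unadjusted p under 0.05 and 99, 94, 99 and 103 by DESeq2. Without 2w replicate 1 it called 1 at 2w. From 5w to the late stages matrix genes rose (median 1.22, 40 of 44 positive, camera adjusted p = 9.27e-08, adjusted p = 0.0977 with an estimated correlation, 0 adjusted over the list alone). The genes named beforehand ran from 0.09 (Pecam1) to 0.61 (Vwf). Here edgeR called 0 genes, with 1506 at an unadjusted p under 0.05, 126 by DESeq2, 1 without 5w replicate 5 and 2 without 8w replicate 1. Thinned to 2000 UMIs, 25 genes passed at 2w. Among them was Ccl5 (6.12 ± 1.12, adjusted p = 0.000371), a chemokine of T and NK cells. Ccl5 stood at 2197 CPM in 2w replicate 2 and 78.6 CPM in 2w replicate 1 without thinning, against 0.895 and 2.10 CPM at 0w. At 11w 91 passed, among them Vwf (3.35 ± 0.80, adjusted p = 0.00866) and Sele (5.85 ± 1.24, adjusted p = 0.00201). These counts fell to 0, 0, 1 and 0 at 2w and to 3, 6, 1 and 1 at 11w without 0w replicate 1, 0w replicate 2 and replicates 1 and 2 of the later stage in turn.

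In macrophages, the list of antigen presentation genes stood higher than at 0w at 2w, 5w and 8w, and that of recruited monocytes at 11w, with no single gene past the test. MHC class II genes rose in MP at 2w (median 1.49, 9 of 9 positive, camera adjusted p = 0.00637, adjusted p = 0.83 with an estimated correlation). They rose at 5w (median 0.87, 8 of 9 positive, adjusted p = 0.0107, adjusted p = 0.992 with an estimated correlation) and at 8w (median 1.15, 9 of 9 positive, adjusted p = 0.0106, adjusted p = 0.968 with an estimated correlation). These 3 calls were lost without 0w replicate 2 (adjusted p = 0.273, 0.609 and 0.595). The 2w call was also lost without 2w replicate 1 (adjusted p = 0.601), the 5w call without 5w replicate 1, 2 or 3 (0.0528, 0.139 and 0.0662) and the 8w call without 8w replicate 1 (0.166). With cells thinned to 2000 UMIs, a setting chosen after seeing the data, the 5w and 8w calls were lost (adjusted p = 0.309 and 0.189). H2-Aa, a member of the list, stood at 838, 1739 and 1819 CPM in the MP of 5w replicates 1 to 3 and at 117 to 205 CPM in replicates 4 to 7, on plates G and H, against 641 and 258 CPM at 0w. Genes of inflammatory monocytes rose at 11w (median 0.69, 22 of 29 positive, adjusted p = 0.000306, adjusted p = 0.597 with an estimated correlation), and 0 members passed adjusted over the list alone in each of these 4 tests. In the same MP sums of 11w, mural (0 of 8 positive, adjusted p = 0.000685), endothelial (1 of 7 positive, adjusted p = 0.035) and mesothelial markers (0 of 3 positive, adjusted p = 0.004) fell, with adjusted p = 0.382, 0.597 and 0.381 with an estimated correlation. The mural call was lost with thinned cells (adjusted p = 0.21) and the endothelial call without 0w replicate 2 or 11w replicate 2 (0.211 and 0.463). At 2w sarcomere genes rose in MP (20 of 21 positive, adjusted p = 0.00637, adjusted p = 0.847 with an estimated correlation), a call lost without 0w replicate 1 or 2w replicate 2 (0.0838 and 0.189). At 5w heat shock genes rose (14 of 15 positive, adjusted p = 0.00341, adjusted p = 0.992 with an estimated correlation), a call lost without 0w replicate 2 (0.209), and fibroblast markers fell (0 of 7 positive, adjusted p = 0.00123, adjusted p = 0.992 with an estimated correlation), a call lost with thinned cells (0.145). Ccr2, the receptor that draws monocytes from blood, had log2 fold changes of 1.59 ± 1.28, 2.71 ± 1.21, 3.52 ± 1.34 and 2.91 ± 1.35 at 2w, 5w, 8w and 11w. Spp1, which encodes osteopontin, was at 5.98 ± 1.78 at 11w (adjusted p = 0.863), with 658 CPM in 11w replicate 2 and 38.4 CPM in 11w replicate 1. At 11w Lgals3 was at 1.19 ± 0.97, Cd68 at 0.21 ± 0.79, H2-Aa at 0.27 ± 1.23 and Lyve1, a marker of resident macrophages, at -0.13 ± 0.69, after -1.28 ± 0.70 at 2w. The 6 genes named beforehand ran from -0.51 (Lyve1) to 2.71 (Ccr2) at 5w and from -0.75 (Lyve1) to 3.52 (Ccr2) at 8w.

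From 5w to the late stages, MP genes of inflammatory monocytes rose (median 0.36, 18 of 29 positive, camera adjusted p = 0.000818, adjusted p = 0.563 with an estimated correlation, 1 adjusted over the list alone). Spp1 was at 3.94 ± 0.93 (adjusted p = 0.299), Ly6c2 at 2.34 ± 0.78, Vcan at 2.33 ± 0.92 and Trem2, a lipid receptor, at 1.54 ± 0.69. The 6 genes named beforehand ran from -0.34 (Cd68) to 3.94 (Spp1). Matrix genes (median 1.17, adjusted p = 2.03e-14, 4 adjusted over the list alone) and fibroblast markers (median 1.15, 7 of 7 positive, adjusted p = 0.000104, 0 adjusted over the list alone) rose in the same sums. Mural (1 of 8 positive, adjusted p = 0.00262) and mesothelial markers (0 of 3, adjusted p = 0.0151) fell. Each had adjusted p = 0.41 with an estimated correlation. The mural call was lost with thinned cells (adjusted p = 0.205) and the mesothelial call without 8w replicate 1 or 11w replicate 2 (0.0539 and 0.0708). Genes of resting fibroblasts rose (20 of 20, adjusted p = 2.83e-07, adjusted p = 0.435 with an estimated correlation). T cell markers fell (1 of 4, adjusted p = 0.0456, adjusted p = 0.795 with an estimated correlation), a call lost with thinned cells (0.081), with RLE factors (0.0696) and without 5w replicate 1, 2, 3 or 7, 8w replicate 2 or 3, or 11w replicate 2 (0.0507 to 0.171). edgeR called 0 of 13752 MP genes in each of the 5 contrasts, with 459, 779, 842, 717 and 1409 at an unadjusted p under 0.05 and 1, 4, 3, 0 and 123 by DESeq2. It called 6 at the late stages without 5w replicate 1.

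In T cells, cell cycle genes fell from 5w to the late stages. Subclusters were not separated, and 30 of 36 T5 cells were on plate F, which held 45 T cells. Top2a, which untangles replicated DNA, fell by 4.33 on the log2 scale (± 0.93 SE, adjusted p = 0.0415), with 479, 556 and 975 CPM at 5w against 0, 4.29 and 6.19 CPM in 3 late mice and 428 CPM in 8w replicate 1. Pcna, the clamp of DNA polymerase, fell by 3.53 (± 0.73 SE, adjusted p = 0.0286). Cdkn3, Ccnb1 and Neil3, of dividing cells, were called too and stood at 0 CPM in all 4 late T mice, with up to 134, 966 and 278 CPM at 5w. As a group the T cell cycle genes fell (0 of 27 positive, camera adjusted p = 4.28e-20, adjusted p = 0.0332 with an estimated correlation; 4 called and 21 adjusted over the list alone). In cells thinned to 2000 UMIs, a setting chosen after seeing the data, their summed level was 8840 and 10400 CPM in 5w replicates 2 and 3 (plate F), 3020 CPM in 5w replicate 1 and 500 to 1010 CPM in the late mice. Against 0w, they rose at 2w and 5w (24 of 27 positive in each, adjusted p = 0.000666 and 8.11e-09, adjusted p = 0.531 and 0.169 with an estimated correlation) and fell at 8w and 11w (6 and 8 positive, adjusted p = 0.0312 and 0.00465, adjusted p = 0.59 and 0.603 with an estimated correlation). Adjusted over the list alone, 0, 0, 0 and 4 passed. With thinned cells the 2w and 8w calls were lost (adjusted p = 0.0521 and 0.382). The 8w call was also lost without 0w replicate 1, 0w replicate 2 or 8w replicate 3. The 11w call was lost without 0w replicate 1 or 11w replicate 1.

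Among the genes that rose in T cells from 5w to the late stages were Ankrd1 (5.13 ± 0.80, adjusted p = 0.00716), Csrp3 (4.30 ± 0.86, adjusted p = 0.022) and Ttn (3.42 ± 0.70, adjusted p = 0.0263), all muscle genes. Others were Mgp, a matrix protein of vessels and fibroblasts (4.03 ± 0.70, adjusted p = 0.00716), and H2-Ab1, an MHC class II gene (3.21 ± 0.56, adjusted p = 0.00716), the last named after its value was seen. Clu, also called, stood at 0 to 1.82 CPM at 5w and 10.1 to 245 CPM at the late stages. The sarcomere list rose (median 1.91, 19 of 21 positive, camera adjusted p = 1.16e-16, adjusted p = 0.124 with an estimated correlation, 9 adjusted over the list alone). MHC class II genes (median 2.61, 8 of 8 positive) and B cell markers (median 3.65, 5 of 6 positive) rose too. They had adjusted p = 1.04e-11 and 5.2e-07, 0.0912 and 0.0332 with an estimated correlation, and 6 and 3 adjusted over the list alone. Mitochondrially encoded genes rose as well (median 2.35, 10 of 10 positive, adjusted p = 6.62e-17, adjusted p = 0.124 with an estimated correlation, 10 adjusted over the list alone). T cell markers fell (median -2.38, 1 of 6 positive, adjusted p = 0.00544, adjusted p = 0.316 with an estimated correlation, 3 adjusted over the list alone), a call lost without 8w replicate 3 or 11w replicate 2 (adjusted p = 0.082 and 0.0624). Genes of resting fibroblasts (16 of 20 positive, adjusted p = 2.92e-07), lymphatic markers (6 of 6 positive, adjusted p = 0.000471) and endothelial markers (5 of 7 positive, adjusted p = 0.00323) rose in these T sums as well. They had adjusted p = 0.131, 0.143 and 0.316 with an estimated correlation, and with thinned cells, the last 2 calls were lost (adjusted p = 0.0982 and 0.105). The endothelial call was also lost without 5w replicate 2 (0.0631).

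Against 0w, 8 T cell genes passed at 5w, all lower. Mgp fell by 4.04 on the log2 scale (± 0.74 SE, adjusted p = 0.0312), Myh6 by 3.54 (± 0.68, adjusted p = 0.04) and Hrc, a calcium-binding protein of muscle, by 6.26 (± 1.22, adjusted p = 0.0403). Scgb3a2, a secretoglobin of airway cells, fell by 8.30 (± 1.49, adjusted p = 0.0312) and had been at 686 CPM in 0w replicate 1 and 50.01 CPM in 0w replicate 2. Without 0w replicate 1 its adjusted p was 0.959. The other 4 were the mitochondrial mt-Nd4, mt-Cytb and mt-Rnr1 and the predicted gene Gm13340. Genes of calcium handling and conduction fell as a group in T (median -3.55, 0 of 18 positive, camera adjusted p = 2.23e-14, adjusted p = 0.0275 with an estimated correlation, 8 adjusted over the list alone), with 1 member called. Sarcomere genes fell too (median -2.60, 0 of 21 positive, adjusted p = 5.97e-19, adjusted p = 0.169 with an estimated correlation, 15 adjusted over the list alone).

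edgeR called 0, 8, 0, 0 and 30 of 12109 T cell genes at 2w, 5w, 8w, 11w and the late stages against 5w (16 higher and 14 lower in the last), with 836, 937, 1128, 845 and 1954 at an unadjusted p under 0.05 and 94, 99, 186, 15 and 565 by DESeq2. The median log2 fold change of all T genes was -0.59 at 8w, -0.79 at 11w and -0.83 at the late stages. With RLE factors the 5w count was 0, with adjusted p from 0.057 to 0.0967 for Mgp, Myh6, Hrc and Scgb3a2. The 5w count was 35 without 0w replicate 1, 25 without 5w replicate 3 and 0 without 5w replicate 1 or 5w replicate 2. At 2w it was 2 without 0w replicate 2, at 8w 2 without 0w replicate 2 and 42 without 8w replicate 1. The late count was 18 without 5w replicate 2, 67 without 8w replicate 1 and 9 without 11w replicate 2. At 5w, these 4 genes lost their calls without 5w replicate 1 (adjusted p 0.0614 to 0.129) or 5w replicate 2 (0.124 to 0.178), and Myh6 and Hrc also without 0w replicate 2 (0.0721 and 0.0886). Of the late calls, Pcna lost its call without 5w replicate 1, 2 or 3, 8w replicate 3 or either mouse at 11w (adjusted p 0.0518 to 0.282). Top2a lost it without 5w replicate 1 or 3 or either mouse at 11w. Csrp3 lost it without 5w replicate 1 or 2 or 11w replicate 2 and Ttn without 5w replicate 2 or 11w replicate 2. Without mitochondrial genes, Hrc at 5w and Pcna and Top2a at the late stages lost their calls (adjusted p 0.0614, 0.0534 and 0.0587). With cells thinned to 2000 UMIs and plate F left out, settings chosen after seeing the data, the adjusted p was 0.443 for Top2a and 0.637 for Pcna and H2-Ab1.

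**Figure D3:**
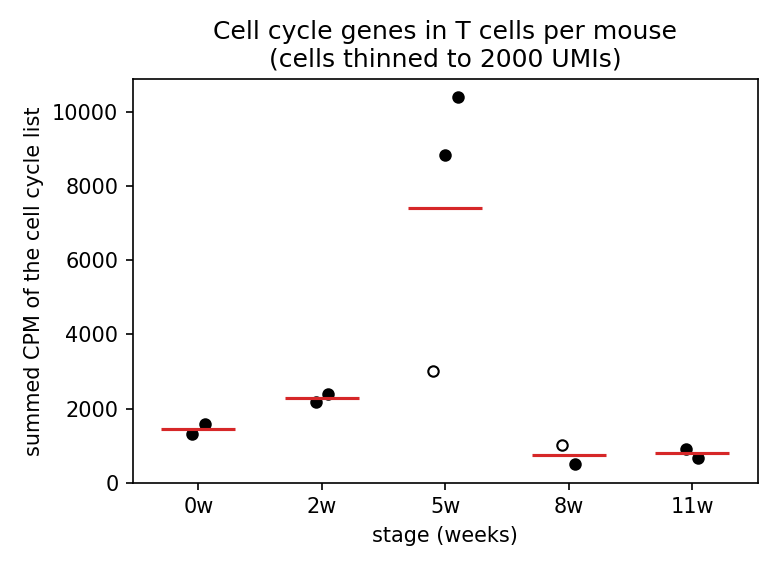
Summed CPM of the 27 cell cycle genes in the T cells of each of the 11 mice, with cells thinned to 2000 UMIs, by stage in weeks; each point is a mouse, open circles are the 2 mice of plate E and red bars are stage means. The 2 mice of plate F at 5w lie at 8840 and 10400 CPM, 5w replicate 1 at 3020 CPM, and the other 8 mice between 500 and 2380 CPM.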

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

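The tests of plate F and of immature T cells, the count of splits that keep plates whole, the grouping of plates by their share of cardiomyocytes, and the fits without plate E or with thinned cells were chosen only after the results they bear on were seen. Ccr2 in MP stood at 200 CPM in 5w replicate 2, far from the other 6 mice of 5w, which lay between 0 and 82.5 CPM; 22 groups of mice were tested in this way, and about 1 in 20 such groups stands out by chance. In CM, 3 genes, and in T cells, 30 genes had effects at 8w and 11w that differed from those at 5w by the test of the difference itself.

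Other splits of the mice of 5w, 8w and 11w into groups of the same sizes show whether chance can be excluded. In CM, 1 of 100 splits, the real one, called as many as 3 genes, and the highest other called 1, so chance can be excluded if mice are taken as exchangeable. Without plate E the same held of 1 of 35 splits, with 419 genes against 12. Mice of a plate come in pairs, however, and most of these splits part them: 6 of the 100 and 3 of the 35 keep the mice of each plate of 1 stage together, which is too few for a share under 0.05, and the highest others among them called 0 genes in both. In T cells, 2 of 35 splits called 30 genes or more and the highest other called 42, so chance cannot be excluded; that split set 8w replicate 3 and both mice of 11w against the mice of plates E and F, so it follows plates. With T cells thinned to 2000 UMIs, 1 of 35 splits called 21 genes, against 7 in the highest other, and the 7 splits that keep those plates whole are again too few for a share under 0.05. That count of 21 was 1 without 5w replicate 2 and 1 without 5w replicate 3, both of plate F, and 41, 70, 53 and 35 without 5w replicate 1, 8w replicate 1, 8w replicate 3 and 11w replicate 1. In FB, EC and MP the real count was 0, which all 56, 100 and 100 splits reached, and the highest others called 4, 8 and 45. Thinned to 2000 UMIs, 9 of 56 splits in FB, 63 of 100 in EC and 11 of 100 in MP called as many as the real 9, 3 and 2 genes, and the highest others called 37, 117 and 244, several times the real counts. Such splits point to a structure of the samples: the EC split set both mice of plate E and both of 11w apart, and the MP split set the mice of plates G and H with the mice of 8w.

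More CM genes passed once the mice of plate E were left out, 419 against 3. Among the other 14 pairs of 1 mouse of 5w and 1 of 8w, the highest count was 117, which argues against any pair having this effect. Pairs that kept 5w replicate 1 called at most 2, so the rise needs that mouse left out. RNA or cells of other types in the CM sums of plate E stay open. Both its mice lay above the other 12 in markers of FB, EC and MP (9640 and 7890 against at most 3450 CPM). Plate differences that follow the stages stay open too. Of 345 called genes with at least 10 UMIs on plate E, 42.9% had the same sign between its 2 mice, against 47.4% of all genes. The 419 genes may hold plate differences beside any stage effect, which was not separated from plate.

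Cardiomyocyte transcripts were lower in FB and T cells at 5w than at 0w and at 8w and 11w. The 5w mice fitted in these 2 types were on plates E and F, while the 0w and late sums also held cells of plates A, J and K. Free cardiomyocyte RNA on plates with many cardiomyocytes stays open as a candidate explanation: Spearman rho between the marker CPM in FB, in cells thinned to 2000 UMIs, and the share of cardiomyocytes was 0.85 over 12 plates, but these fall into separate clusters, so the pooled value is not read as a relation. Within the 6 plates under 20% cardiomyocytes no relation held over the 8 exact permutation tests: rho = 0.26 (p = 0.658, adjusted p = 0.658) and r = 0.32 (p = 0.597, adjusted p = 0.658) in FB, rho = 0.89 (p = 0.0333, adjusted p = 0.133) and r = 0.52 (p = 0.114, adjusted p = 0.228) in EC, rho = 0.94 (p = 0.0167, adjusted p = 0.133) and r = 0.55 (p = 0.103, adjusted p = 0.228) in MP, and rho = 0.54 (p = 0.297, adjusted p = 0.475) and r = 0.38 (p = 0.464, adjusted p = 0.619) in T, with r at -0.04, 0.20, 0.10 and -0.14 without plates D and F. An expression of these genes by the other cell types at 0w or the late stages was not tested apart from it.

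Cell cycle genes were higher in T cells at 5w than at 0w and at the late stages. Whether this belongs to plate F alone is not settled, since a single fitted 5w mouse lay off that plate. In cells thinned to 2000 UMIs, 5w replicate 1, on plate E, stood at 3020 CPM (Poisson interval 2590 to 3500 from 175 UMIs). It lay above 0w (1300 and 1570) and the late mice (500 to 1010). It lay 1.27 times above the highest other, of 2w (2380, upper bound 2610), with overlapping intervals. Immature T cells of the thymus stay open, since the 8 thymocyte genes summed to 2470 and 3020 CPM in the mice of plate F, both above the highest other stage (2140 CPM in 0w replicate 1). A division of T cells in the heart at 5w was not tested apart from these.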

How the results depend on the processing

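The fits on mean log values, logs of means and shares of cells with a UMI, those with thinned cells and those without plates were chosen after seeing the data; the other settings were not. Counts are given in the order 2w, 5w, 8w and 11w against 0w and the late stages against 5w, against 0, 0, 0, 0 and 3 in CM, 0 throughout in FB and MP, 0, 1, 0, 0 and 0 in EC and 0, 8, 0, 0 and 30 in T from edgeR; a type left out kept each count within 1.5 times. The cause of these differences was not tested.

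With RLE factors, EC had 0 in every contrast and T had 0, 0, 0, 0 and 38. RLE moved the median log2 fold change of all genes by over 0.1 in FB at 5w (0.06 to 0.16), EC at 2w (0.01 to -0.30), 5w (-0.29 to -0.09), 11w (-0.08 to -0.19) and late (0.16 to -0.09), MP at 5w (-0.04 to 0.27) and late (-0.13 to -0.37) and T at 2w (0.01 to -0.12), 5w (0.03 to 0.29), 8w (-0.59 to -0.49) and 11w (-0.79 to -0.46). With no low-count filter the counts were 7, 86, 26, 95 and 470 in CM, 38, 44, 62, 43 and 137 in FB, 2, 14, 2, 12 and 146 in EC and 5, 42, 14, 1 and 71 in T. Without mitochondrial genes they were 0, 4, 0, 0 and 11 in T. With at least 20 cells they were 16 at 2w, 38 at 5w and 6 at 11w in T, and this setting gave no value for EC at 5w and late and T at 8w and late. DESeq2 gave 12, 91, 4, 144 and 474 in CM, 454, 286, 286, 223 and 227 in FB, 99, 94, 99, 103 and 126 in EC, 1, 4, 3, 0 and 123 in MP and 94, 99, 186, 15 and 565 in T.

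Mean log values gave 46, 1271, 806, 2977 and 10 in CM, 85, 52, 56, 89 and 44 in FB, 60, 89, 59, 79 and 0 in EC, 7, 10, 8, 8 and 0 in MP and 13, 102, 23, 19 and 724 in T. Logs of means gave 0, 13, 0, 75 and 48 in CM, 57, 38, 46, 61 and 23 in FB, 23, 69, 39, 38 and 0 in EC, 2, 4, 3, 3 and 0 in MP and 7, 14, 5, 11 and 44 in T. Shares of cells with a UMI gave 3, 3531, 3056, 3839 and 5 in CM, 62, 123, 31, 473 and 2483 in FB, 2, 4, 2, 2 and 0 in EC, 0, 1, 1, 0 and 0 in MP and 0, 15, 0, 28 and 2055 in T. Thinned to 1000 UMIs, counts were 0, 2, 0, 2 and 7 in CM, 11, 1, 1, 13 and 17 in FB, 44, 70, 64, 104 and 3 in EC, 0, 2, 0, 0 and 0 in MP and 1, 22, 1, 0 and 20 in T. Thinned to 2000 they were 0, 0, 0, 0 and 13 in CM, 8, 1, 0, 15 and 9 in FB, 25, 73, 82, 91 and 3 in EC, 0, 1, 0, 0 and 2 in MP and 0, 16, 0, 0 and 21 in T, and in a second draw 0, 0, 0, 0 and 12 in CM, 6, 1, 0, 19 and 24 in FB, 11, 59, 89, 99 and 2 in EC, 0, 1, 0, 1 and 0 in MP and 0, 26, 0, 0 and 9 in T. Thinned to 4000 they were 0, 0, 0, 0 and 9 in CM, 7, 1, 1, 18 and 13 in FB, 1, 15, 48, 51 and 4 in EC, 0, 0, 0, 0 and 2 in MP and 0, 13, 1, 0 and 27 in T.

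Without plate E, CM had 0, 84, 3, 135 and 419, with cells also thinned to 2000 UMIs 17, 185, 19, 319 and 553, and to 1000 UMIs 30, 172, 20, 286 and 400. Thinned to 2000 UMIs without plate F, counts were 17, 0, 2, 26 and 0 in FB, 37, 57, 76, 101 and 2 in EC, 0, 3, 0, 1 and 3 in MP and 14, 0, 15, 13 and 2 in T. Thinned in the same way and without plates G, H and K they were 10, 4, 0, 27 and 14 in FB, 36, 14, 71, 98 and 1 in EC, 0, 97, 0, 57 and 2 in MP and 0, 5, 0, 2 and 3 in T. Thinned in the same way and on plates with mostly non-cardiomyocytes they were 5, 1, 0, 21 and 3 in FB, 44, 8, 63, 105 and 0 in EC, 0, 1, 0, 5 and 2 in MP and 20, 23, 3, 17 and 39 in T.

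With each mouse left out in turn, a stage left with 1 mouse being assumed to vary like the others, CM counts ran from 0 to 13 at 5w and 0 to 70 late, FB from 0 to 2 at 5w, 0 to 1 at 8w and 0 to 8 late, EC from 0 to 1 at 2w, 0 to 0 at 5w and 0 to 2 late, MP from 0 to 6 late, and T from 0 to 2 at 2w, 0 to 35 at 5w, 0 to 42 at 8w and 9 to 67 late, and were 0 in the other contrasts. Type shares past the threshold ran from 0 to 2 and subclusters from 0 to 4, and 0 subclusters passed when 0w was set against all later stages. Gene lists past the threshold ran from 240 to 339 around 295, and were 3 with an estimated correlation, 290 with RLE factors and 259 in the added fits.

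The replicate numbers did not pair the mice: deviations correlated over 0.1 in 1 of 16 pairs in CM, 1 of 21 in FB, 1 of 17 in EC, 1 of 21 in MP and 0 of 17 in T. Most mice correlated best with a mouse of their own replicate number in CM (7 of 9), FB (10 of 12), EC (8 of 11) and T (8 of 11), but not in MP (4 of 12). With the number as a replicate block, counts were 0, 121, 0, 0 and 389 in CM, 0, 0, 0, 0 and 6 in FB, 1, 0, 0, 0 and 0 in EC, 0, 53, 0, 1 and 42 in MP and 10, 34, 4, 4 and 77 in T. Signs turned with the block for Nppb in CM at 5w (-6.82), Myh6 and Atp2a2 in CM late (1.82 and 0.52), and Postn at 5w (-0.25) and Acta2 at 8w (-0.68) in FB.

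The other signs that turned, all of genes that had not passed in the tests fixed beforehand, are given here, with plates left out only from cells thinned to 2000 UMIs. They were Acta1 in CM at 11w on mean log values (-0.70) and Myh6 in CM late without 8w replicate 1 (0.04). In FB, Postn at 5w turned without 0w replicate 1 (-0.10), without 5w replicate 2 (-0.38), on logs of means (-0.05), thinned to 4000 UMIs (-0.05), in the second draw (-0.18) and without plate F (-1.40), Col3a1 at 5w without plate F (-0.35) and Acta2 at 8w without 8w replicate 3 (-1.32). In EC, Vwf at 2w turned thinned to 1000 UMIs (-0.55), to 2000 UMIs (-0.28, also without plate F and without plates G, H and K) and on mostly non-cardiomyocyte plates (-0.43), and Vwf late without plates G, H and K (-0.36) and on mostly non-cardiomyocyte plates (-0.85). In MP at 11w, Lyve1 turned without 0w replicate 1 (0.57), Cd68 on logs of means (-0.01), thinned to 2000 UMIs (-0.09), without plate F (-0.06) and on mostly non-cardiomyocyte plates (-0.52), and H2-Aa without 0w replicate 2 (-0.26) and without 11w replicate 1 (-0.96). With each mouse left out in turn, Myh6 late ran from -0.55 to 0.04, Postn from -0.38 to 0.78, Acta2 from -1.32 to 1.73, Lyve1 from -0.62 to 0.57 and H2-Aa from -0.96 to 1.09.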

Other observations

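The lists described here were picked from the tests fixed beforehand after their results were seen, and no further test was run. In MP at 11w, interferon response genes rose against 0w (median log2 fold change 1.07, 24 of 30 positive, camera adjusted p = 8.95e-05; adjusted p = 0.597 with an estimated correlation), while genes of fatty acid oxidation (median -1.34, 1 of 27 positive, adjusted p = 0.000306) and of the tricarboxylic acid cycle (median -1.02, 0 of 20 positive, adjusted p = 0.000306) fell, each with adjusted p = 0.597 with an estimated correlation; the last call was lost without 11w replicate 1 (adjusted p = 0.0633). In T at 8w and 11w, B cell markers rose against 0w (medians 3.15 and 2.87, 6 of 6 positive in each, adjusted p = 1.84e-06 and 5.83e-06; adjusted p = 0.12 and adjusted p = 0.168 with an estimated correlation), with 3 and 0 adjusted over the list alone; in the other lists of this paragraph, 0 members passed adjusted over the list alone.

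Gm12155 in CM, called at the late stages against 5w, stood at 333 CPM ± 9.41 (SD, n = 2) at 0w, 31.6 ± 10.4 (n = 2) at 2w, 69.2 ± 40.1 (n = 5) at 5w, 283 ± 165 (n = 3) at 8w and 1578 ± 306 (n = 2) at 11w. These values are TMM-scaled. In CPM pooled over mice without TMM factors, Gm12155 stood at 460 at 0w and 477 at 11w, and in cells thinned to 2000 UMIs at 1480 and 4530. GN cells made up 0.902% ± 0.0940 (n = 2) of annotated non-cardiomyocytes at 0w and 9.38% ± 9.59 (n = 3) at 8w, and this share did not pass across stages (permutation test, adjusted p = 0.677). Globin genes took a median of 55.4% of the non-mitochondrial UMIs of the 30 CM of plate I.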
